A study of Homo sapiens with 4 samples.

How the data were processed

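Gene expression was measured on 4 one-colour Agilent arrays, 1 for each combination of 2 human colorectal cancer cell lines, CW2 and HCT116, and 2 small interfering RNAs, a control siRNA (siCont) and an siRNA against VSNL1 (siVSNL1). Total RNA was extracted with a column kit and labelled with Cy3, per the labels' protocols. Arrays were read with Agilent Feature Extraction 9.1, per the submitters' processing notes. The normalization and filtering that followed are not given in the sources used here.

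The values, read here as log2 ratios, are those of the authors' deposited value table, which has 34183 rows. Both columns of the control siRNA are exactly 0 at every row, so each siVSNL1 column is a ratio to the control array of its own line. The log base is not stated. Base 10 would need ratios beyond the range of a scanner, and the values were read as log2. A natural log was not excluded, and every fold value and fold count rests on the reading as log2. The direction, siVSNL1 over control, is likely rather than stated: it rests on the value standing in the siVSNL1 column while the control column is 0. The scaling between arrays is unknown. The medians of the siVSNL1 columns over probes were -0.11 in CW2 and -0.09 in HCT116, and those of the control columns are 0 by construction. Signal levels, detection flags and scan batches were not analysed here, and only the number of arrays can be given as a limit on precision.

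Of the rows, 56 are control features of the array and 34127 are probes. The control features were kept out of all counts and tests of probes, except the search over row shifts, which ran on all rows of the table. The probe IDs are not paired with gene names in the sources used here, and 0 probes could be given a gene symbol. VSNL1 itself and the 27 gene lists fixed before the data were examined were therefore not evaluated, and the rule for named genes (VSNL1, the largest changes shared by both lines, the largest changes of each line and the list members with the largest changes) named no gene. The probes with the largest ratios in CW2 are given by ID.

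The planned design assumed signal levels. With ratios only, the filter on dim probes, the comparison of the 2 control arrays and the choice of 1 probe per gene could not be made, and all probes entered. Within a line there is 1 array per group, so each ratio has no replicate check and no p-value was computed. Probes past a 2-fold ratio were counted each way. Across the lines, limma 3.58.1 in R 4.3.3 was fitted to all 4 columns with the cell line as a block, which leaves 1 residual degree of freedom before moderation, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The pairing comes from the cell line. The counts of probes past 2-fold in both lines were set beside the overlap of independent lists and beside 1000 random orders of the HCT116 values.

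A narrow band of ratios was defined in each line after the values were seen: the 0.01-wide bin with the most probes and the neighbouring bins holding at least 0.25 of its number. Shares of probes have 95% Wilson intervals, and odds ratios have 95% Woolf intervals. These treat probes as independent draws, which they are not. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The limma fit was tested on simulated data: the real values in random order with 200 probes changed in both lines. Of 50 probes changed by a log2 ratio of 4, 0 were called, although 50 had an unadjusted limma p under 0.05. The fit could not call changes of this size. The median estimate was 4.03, which follows from adding the same change to both lines. The row search and the odds ratio were also tested on simulated rows, where a shift and a reversal were each found with r = 0.498. In that simulation 50% of rows copied the CW2 band membership, which gave an odds ratio of 11.4. A weaker link between the lines was not simulated. Median centring, other fold thresholds, a robust variance prior, an unblocked fit and the removal of the narrow band were tried as alternatives.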

Results

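The study asked which genes respond when VSNL1 is depleted in colorectal cancer cells. VSNL1 encodes visinin-like protein 1, a calcium-binding protein of the neuronal calcium sensor family. CW2 and HCT116, which are human colorectal cancer cell lines, received either a control siRNA or an siRNA against VSNL1, and 1 array was hybridised for each of the 4 combinations. The data comprise, for each line, 1 log2 ratio of the siVSNL1 array to the control array at each of 34127 probes. There were no replicates within a line. Changes are described by probe, since the probes are not paired with genes here, and the depletion of VSNL1 itself was not evaluated.

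In CW2, 616 probes were at least 2-fold higher and 1279 at least 2-fold lower in the siVSNL1 array, 5.55% of all probes. At 4-fold the numbers were 103 higher and 227 lower. The highest ratios were those of A_23_P31739, with a log2 ratio of 5.86 (58.2-fold), and A_33_P3254078, with 5.52 (45.8-fold). The lowest were those of A_33_P3360147, at -5.55 (46.7-fold lower), and A_23_P54681, at -5.21 (36.9-fold lower). The SD of the log2 ratio over probes was 0.485, and the lower and upper quartiles were -0.223 and 0.075. With 1 array per group, none of these ratios can be set against a spread between replicates.

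In HCT116, 782 probes were at least 2-fold higher and 1540 at least 2-fold lower, 6.80% of all probes. At 4-fold the numbers were 74 higher and 207 lower. The highest log2 ratio was 5.16 (35.7-fold). The 3 lowest were -12.54, -10.18 and -8.78, and the next was -5.25. The SD over probes was 0.526, and the lower and upper quartiles were -0.182 and 0.164. These values are given without probe IDs because the match of this column to its IDs was in doubt on the measurements given below. As in CW2, the ratios have no replicate check.

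Lower probes outnumbered higher probes in both lines. They made up 67.5% of the probes past 2-fold in CW2 and 66.3% in HCT116, read as siVSNL1 over control. Were the ratio control over siVSNL1, the same percentages would be those of the higher probes. With each line centred on its median over all probes, -0.11 on the log2 scale in CW2 and -0.09 in HCT116, the shares were 58.2% and 56.9%.

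The ratios of both lines had the same 2-part shape. A narrow band from -0.26 to -0.18 held 8719 probes in CW2 (25.5%), and a band from -0.18 to -0.12 held 7648 probes in HCT116 (22.4%). The other probes spread around a median of -0.01 in CW2 and 0.03 in HCT116. Of the 25 ERCC and ETG control features of the array, 64.0% lay in the band in CW2 and 40.0% in HCT116. These features were picked after the values were seen. Over all 56 control features the shares were 33.9% in CW2 and 37.5% in HCT116. In CW2 the band held 1 of the 18 DCP and 1 of the 10 E1A control features. The match of the HCT116 column to its names was in doubt on the measurements given below.

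**Figure D1:**
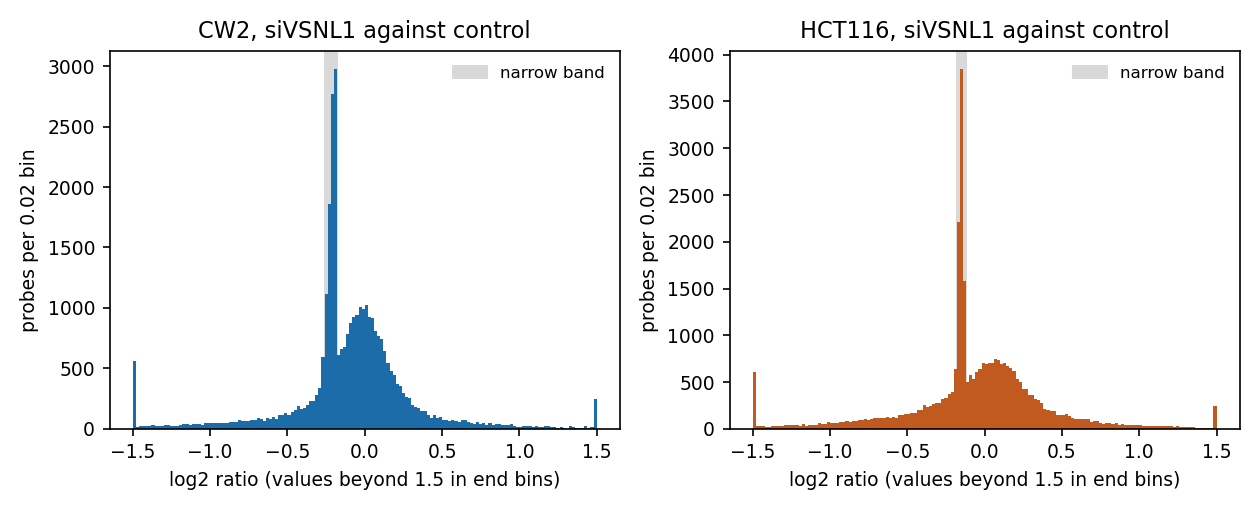
Histograms of the log2 ratio of siVSNL1 to control over 34127 probes in CW2 (left) and HCT116 (right), with the number of probes per bin on the vertical axis, 1 array pair per line, and values beyond the axis gathered in the end bins. The grey stripe marks the narrow band, which held 25.5% of probes in CW2 and 22.4% in HCT116, to the left of a broad peak near 0.

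Compared by probe ID, the 2 lines can show which changes they share only if the HCT116 column matches its IDs. That match was in doubt on the measurements given below, so the values here do not tell whether changes are shared. Of all probes, 14 were at least 2-fold higher in both lines, against 14.1 for independent lists, and 47 were at least 2-fold lower in both, against 57.7. A further 28 were higher in CW2 and lower in HCT116, against 27.8, and 30 were lower in CW2 and higher in HCT116, against 29.3. All 4 counts lay within the central 95% of 1000 random orders of the HCT116 values, which ran from 7 to 22 for higher in both and from 44 to 73 for lower in both. Across probes, which are not independent replicates, Pearson's r between the lines was 0.001 (95% interval -0.010 to 0.012) and Spearman's rho was 0.003. Probes outside both bands, 19740 in number, gave r = 0.001 (-0.013 to 0.015).

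In the limma fit across both lines, with the line as a block, 0 of 34127 probes had a Benjamini-Hochberg adjusted p under the threshold, and the smallest adjusted p was 0.865. By the same limma fit, 720 probes lay under an unadjusted p of 0.05, against 1706 for chance alone under the model; without the block the number was 2982, from a fit whose added degree of freedom comes from the control columns of 0. The fit has 1 residual degree of freedom, and it called 0 of 50 simulated probes at each size up to a log2 ratio of 4 in both lines. The absence of calls therefore does not exclude shared changes of the sizes simulated. Larger changes, or changes in more than 200 probes, were not simulated. The fit also averages the 2 lines by probe ID, so all of these values rest on the match of the HCT116 column to its IDs, which was in doubt.

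Membership of the narrow band was also unrelated between the lines. Both bands held 1980 probes in common, against 1954 for independent lists, an odds ratio of 1.02 (95% interval 0.97 to 1.08). In CW2 the band's share differed between the probe series, named by the start of the probe ID: it was 19.6% (18.9 to 20.3) of 11881 A_23 probes, 21.9% (20.8 to 23.1) of 4901 A_24 probes, 26.8% (24.8 to 28.9) of 1780 A_32 probes and 31.1% (30.4 to 31.8) of 15565 A_33 probes. In HCT116 the shares were 22.5% (21.8 to 23.3), 22.2% (21.0 to 23.4), 23.5% (21.6 to 25.5) and 22.3% (21.6 to 22.9) in the same order. They differed by at most 1.30 percentage points, and 433 of 1000 random orders of the HCT116 values gave a range as wide. Probes past 2-fold followed the same division. In CW2 they made up 3.83% (3.50 to 4.19) of A_23 probes and 7.24% (6.84 to 7.66) of A_33 probes, and in HCT116 6.97% (6.53 to 7.44) and 6.68% (6.29 to 7.08).

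**Figure D2:**
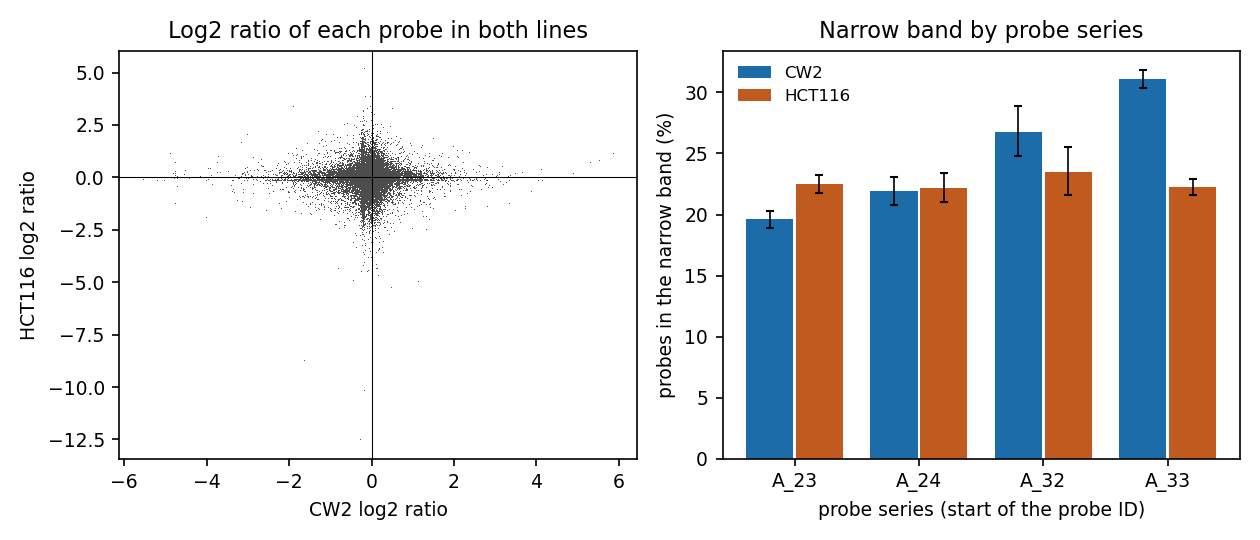
Left, the log2 ratio of each of 34127 probes in CW2 (horizontal) and HCT116 (vertical), 1 point per probe. Right, the percentage of probes of each series in the narrow band, with bars for the lines and 95% Wilson intervals; the CW2 shares run from 19.6% to 31.1%, while the HCT116 shares lie between 22.2% and 23.5%.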

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

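The correlation over all probes and the counts of probes past 2-fold were planned; the tests on the narrow band, the probe series, the row order and the control features were chosen after the results were seen. Probes past 2-fold in opposite directions in the 2 lines numbered 58. Of these, 28 were higher in CW2 and lower in HCT116 (27.8 for independent lists) and 30 the reverse (29.3). The counts were thus near those of independent lists and rest on the match of the HCT116 column to its IDs. They were not tested probe by probe. Among the 56 control features of the array, which were kept out of the counts of probes, 4 were past 2-fold in HCT116 and 1 in CW2. Of all probes, 6.80% were past 2-fold in HCT116 and 5.55% in CW2. By the names of a column whose match to them was in doubt, the HCT116 features were ETG07_105829 at 1.98, ERCC-00171_229 at 1.32, DCP_20_7 at 1.02 and DCP_22_6 at -1.86. The CW2 feature was DCP_1_11 at -1.80. In the other line, ETG07_105829 had -0.16, ERCC-00171_229 had -0.24, DCP_20_7 had 0.91, DCP_22_6 had -0.10 and DCP_1_11 had -0.77.

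The probe values of the 2 lines showed no relation in their correlation, in the counts past 2-fold or in band membership. No constant shift or reversal of the rows gave a larger correlation of band membership than random orders did. The largest over 34183 shifts in each direction was 0.0224, and 20 random orders gave up to 0.0279. The search can find a reordering only if band membership is related between the lines at the true order, which was not established. An HCT116 column whose values are not matched to their probe names is a candidate explanation. The odds ratio of sharing the band was 1.0233, and the HCT116 shares did not differ between probe series by more than random orders do. These values raised the doubt, so they are not a separate test of it. They bear on the names only if the HCT116 band holds the same kind of probes as the CW2 band, which was not established. A difference in biology between the lines does not by itself account for the range of only 1.304 percentage points over series, if the series dependence of CW2 applies to both lines; whether it accounts for the unrelated changes (r = 0.001) cannot be told apart from mismatched names, because that test needs probe identity. For the same reason the correlation outside both bands, 0.0013, leaves open whether dim probes hide a shared response.

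The control features leave the reach of such a mismatch open. Spearman's rho between the lines over the 56 features was 0.0527 (permutation p = 0.700). Pearson's r was 0.237 (permutation p = 0.0837), and -0.0125 without the 2 features farthest from the CW2 median. In HCT116, 37.5% of control features lay in the band against 22.4% of probes (Fisher's exact test, two-sided, p = 0.00990). In CW2 the shares were 33.9% and 25.5% (Fisher's exact test, two-sided, p = 0.167). A random order of every row would seldom give the HCT116 difference. The test takes the control features as a set, so it cannot tell whether each keeps its own name. In CW2 the band held 16 of 25 ERCC and ETG, 1 of 10 E1A and 1 of 18 DCP features. In HCT116 it held 10, 5 and 4 of them. Whether a mismatch is limited to the probe rows is therefore open.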

How the results depend on the processing

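Each line's counts of probes past 2-fold stayed within 1.5 times their reported values under median centring and, in an alternative chosen after seeing the data, with the band left out and each line centred on the remaining probes. They moved with the threshold by construction. At 1.5-fold there were 1518 higher and 2658 lower probes in CW2 and 2188 and 3484 in HCT116, and at 3-fold 209 and 452 in CW2 and 187 and 495 in HCT116. Probes higher in both lines numbered 23 under median centring (21.6 for independent lists), 104 at 1.5-fold (97.3) and 0 at 3-fold (1.15). Probes lower in both numbered 275 at 1.5-fold (271 for independent lists) and 4 at 3-fold (6.56). Probes higher in CW2 and lower in HCT116 numbered 126 at 1.5-fold (155 for independent lists) and 0 at 3-fold (3.03), and the reverse 167 (170.4) and 3 (2.48). The count of 126 lay below the central 95% of 1000 random orders of the HCT116 values (133 to 181), the only 1 of 16 such counts over these settings to lie outside. The odds ratio of sharing the band was 1.0005 with a narrower band. The limma fit called 0 probes under median centring, with a robust prior and with no replicate block, where the paired structure is ignored and the control columns of 0 add a degree of freedom that is not real; the smallest adjusted p ranged from 0.451 to 0.931 over these alternatives. At an unadjusted p under 0.01, 100 probes passed, and 478 with no replicate block. Under 0.05 the unblocked fit gave 2982 probes, against 720 in the blocked fit and 1706 for chance. Without either line no residual degrees of freedom are left, so no test was made. Quantile and loess normalization, level filters, a pseudocount, an intensity trend, probe averaging, gene lists and the comparison of control arrays were not run, because they need signal levels or gene names.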

Other observations

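Median centring was planned; the test on control features and the centring with the band left out were chosen after the results were seen. The narrow band of nearly equal ratios may hold probes at background on both arrays of a line. In CW2, 64.0% (95% Wilson interval 44.5 to 79.8) of the 25 ERCC and ETG control features lay in it, against 25.5% of probes. In HCT116 it was 40.0% (23.4 to 59.3) of these features against 22.4% of probes. Of the 10 E1A features, 1 lay in the band in CW2 and 5 in HCT116, where that share was above the share of probes and of the ERCC and ETG features. Of the 18 DCP features, 1 lay in the band in CW2 and 4 in HCT116. The ERCC and ETG features, 25 of the 56, were picked after the values were seen. ERCC features target external spike-in RNAs, and whether such RNA was added is not given in the sources used here, which limits this reading. If the reading holds in CW2, the band's centre below 0 there would be an offset of background and not a change in transcripts. The HCT116 features cannot extend it to that line, since the match of its column to its names was in doubt.

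The excess of lower over higher probes past 2-fold, which would be an excess of higher probes if the ratios ran the other way, depended in size on where each line was centred. Centring on the median of all probes lowered the share of lower probes to 58.2% in CW2 and 56.9% in HCT116. With the band left out and each line centred on the remaining probes it was 66.7% and 69.1%. The medians subtracted in that centring were only -0.01 and 0.03, so it decides nothing about the centre as a cause. With 1 array per group, a lower overall yield or quality of both siVSNL1 arrays remains open, or of both control arrays if the ratios ran the other way. No biological explanation was tested.

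The 3 lowest HCT116 ratios, at -12.54, -10.18 and -8.78, stood apart from the next, at -5.25. The lowest of them is a 5948-fold difference. Without signal levels, detection flags or replicates, it cannot be told whether these 3 ratios reflect transcripts or a fault of an array. The lowest CW2 ratio was -5.55.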
